A study of Mus musculus with 2 samples.

How the data were processed

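H3K36me3 ChIP-seq was performed, per the labels, on neural tube of mouse embryos (strain B6NTac;B6NCrl/Lap) at embryonic day 14.5, in 2 biological replicates of 1 group. Replicate 1 pooled 24 embryos and replicate 2 pooled 34, male and female together. The values come from 4 peak lists in the narrowPeak format, on build mm10 per the labels: the authors called peaks in each replicate by itself, on the reads of both replicates pooled, and kept a replicated list drawn from the pooled list. Per the metadata deposited with the samples, the list of replicate 1 was derived from its filtered alignments and 2 other files, and that of replicate 2 from its filtered alignments and 1 other file. What these other files hold is not stated there, and the aligner, the peak caller and their settings are not given in the sources used here.

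The display score of each peak was set by the authors and runs from 10 to 1000 within each deposited list; it was not used. The fold enrichment of each peak is the signal value as deposited by the authors, on a linear scale, and what it is relative to is not stated in the sources used here. The −log10 p and −log10 q of each peak are the authors' values within its own deposited list, with a minimum −log10 p of 2.07 in replicate 1 and 2.03 in replicate 2, so that the authors' threshold was permissive. A peak's score, fold and p were used only to describe, rank or filter peaks within its own list. The lists hold no read counts, the sequencing depth is unknown, and no interval that needs it is given. Every value per gene rests on which bases the authors called as peaks, not on the strength of the signal. The 2 replicate lists shared 1 peak with the same start and end, so they were treated as separate libraries.

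Peaks on the 19 autosomes, X and Y were used, and 2 peaks in each replicate list on unplaced sequence were left out. Genes were taken from the GENCODE M21 annotation, on the same assembly as the peaks. The coverage of a gene is the percent of bases from its annotated start to its annotated end that peaks of a list overlap. Of 21911 protein-coding genes with a unique symbol, the 20327 of at least 2 kb were measured, and 27 duplicate symbols were dropped. A gene was called marked when its coverage was at least 20% in both replicates. Values are given as the mean and SD over the 2 replicates. Coordinates are 1-based.

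The overlap of the replicate lists was counted for peaks that share at least 1 bp, with chance taken from 1000 circular shifts of a list along each chromosome (permutation test, one-sided). Base pairs of peaks in gene bodies, exons, introns, regions within 1 kb of a TSS, 5 kb downstream of gene ends and sequence outside all annotated genes were compared with 1000 circular shifts (permutation test, two-sided), with Benjamini-Hochberg adjustment over features and replicates. Position along genes was measured in 10 equal bins and 5 kb flanks, in genes of at least 5 kb that overlap no other protein-coding gene. The last 5 bins against the first 5, and exons against introns without the first exon (at least 100 bp of each), were tested by 100000 sign flips across genes (permutation test, two-sided). The share of marked genes in 21 gene lists, and on X against autosomes, was tested by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists at a threshold of 0.05. Every Fisher's exact test here counts genes, which are not independent replicates, so its p describes these libraries. The coverage of a list was also set against 10000 random lists matched on gene length. These choices, the gene lists, the marked-gene minimum and the rule for naming genes were fixed before the data were examined.

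The rule for named genes took, in each list, up to 4 marked members with the highest mean coverage and 2 with the lowest, ties being broken by name. It added the 10 genes with the most base pairs in the replicated list, the 10 genes with the highest authors' fold in a peak of that list, and the 3 genes with the largest difference between replicates in each direction. Genes named outside this rule are said to be so where they appear.

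Alternatives chosen in advance were peaks with −log10 q of at least 2, equal numbers of peaks, an overlap of at least 50%, independent placement of peaks and the share of the genome as chance, minimum coverages of 10% and 40%, each replicate alone, the replicated list, no minimum length, and only genes that overlap no other. Alternatives added after the data were seen were equal covered base pairs, 12 gene lists combined, exons and introns without repeats or in the 3-prime part of genes, and chance within gene bodies. No group was compared with another, so no batch between groups could arise, and the labels give no date or batch for the libraries.

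The code was tested on simulated data. It called 100% of 200 genes simulated as marked and 0% of 15700 others. The simulated genes were drawn with coverage well above the 20% minimum over a sparse background, so calls near the minimum were not tested. With peaks drawn evenly along 200 genes, the difference between the sides of the gene was 0.292 percentage points (permutation p = 0.756, two-sided), and it was 30.0 when peaks were drawn towards the 3-prime end. Exons minus introns came to 0.0747 percentage points with a standard error of 1.09 over 199 genes with evenly drawn peaks. Peaks placed at random gave folds from 0.982 to 1.009 over the 6 features. Of random gene lists, 1.7% had a p under 0.05 by Fisher's exact test, with the simulated marked genes in place of the real ones. The simulated marked genes were far fewer than the real ones, which makes this test conservative, so the rate may not hold for the real lists. Circular shifts gave a p under 0.05 in 1 of 20 pairs of lists when a list was placed at random. They gave it in 5 of 20 when both lists lay in separately drawn genes. Placement within gene bodies gave it in 0 of 20 pairs whose second list was itself placed at random in gene bodies. That placement was not run on lists in separately drawn genes.

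Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Random draws used the seed 7.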

Results

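H3K36me3, a trimethylation mark on histone H3, is laid down over the bodies of transcribed genes by the methyltransferase SETD2. It was mapped by ChIP-seq in neural tube, the embryonic tissue that forms brain and spinal cord, from mouse embryos at embryonic day 14.5. The 2 libraries formed 1 group of biological replicates, in which replicate 1 came from a pool of 24 embryos and replicate 2 from a pool of 34, each with males and females together. The labels name no second tissue, stage or treatment, so the comparisons were made between the replicates and between genes and regions within them. The authors' list for replicate 1 held 116913 peaks covering 42.05 Mb of the mm10 genome, and that for replicate 2 held 116834 peaks covering 49.0 Mb. The median peak was 282 bp wide in replicate 1 and 318 bp wide in replicate 2. The lists carry no read counts, so the sequencing depth behind each value is unknown.

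The comparison of the replicates asked how far the peaks of the separate embryo pools coincided. Ubr4, which encodes an E3 ubiquitin ligase and lies on chromosome 4 at 139352609 to 139489588, was among the genes most widely covered in both: peaks took up 59.2% ± 3.63 (SD, n = 2) of its body. The region of Ubr4 held 140 peaks in replicate 1 and 132 in replicate 2, split at different places. Genome-wide, 61.9% of the replicate 1 peaks overlapped a replicate 2 peak by at least 1 bp, and 58.5% of the replicate 2 peaks overlapped a replicate 1 peak. The base pairs common to both lists made up 31.3% of those in either list. Peaks with a high −log10 p most often had a partner among all peaks of the other list. In the top quartile 82.5% of replicate 1 peaks and 79.9% of replicate 2 peaks had one, against 46.8% and 39.8% in the lowest quartile. Peaks with a partner were also wider, with a median of 332 bp against 236 bp in replicate 1 and 392 bp against 261 bp in replicate 2. A wider peak meets another more easily, and the share by quartile was not adjusted for width. With both lists limited to peaks of −log10 q of at least 2, the overlap was lower, 52.3% of replicate 1 peaks and 54.7% of replicate 2 peaks. Counting only overlaps of at least 50% of the peak gave 48.7% and 40.8%. Circular shifts of the replicate 2 list along each chromosome gave a mean of 3.56% for the replicate 1 peaks, and none of 1000 shifts exceeded 6.00%, a permutation p of 0.000999, one-sided and the smallest these shifts can give. On simulated lists such shifts called 5 of 20 pairs that shared a preference for gene bodies and no more. Chance was therefore also drawn within gene bodies, where it came to 8.50%. The permutation p was then 0.009901, one-sided and the smallest that 100 placements can give. That placement was not simulated on lists in separately drawn genes, so it may share this leniency.

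**Figure D1:**
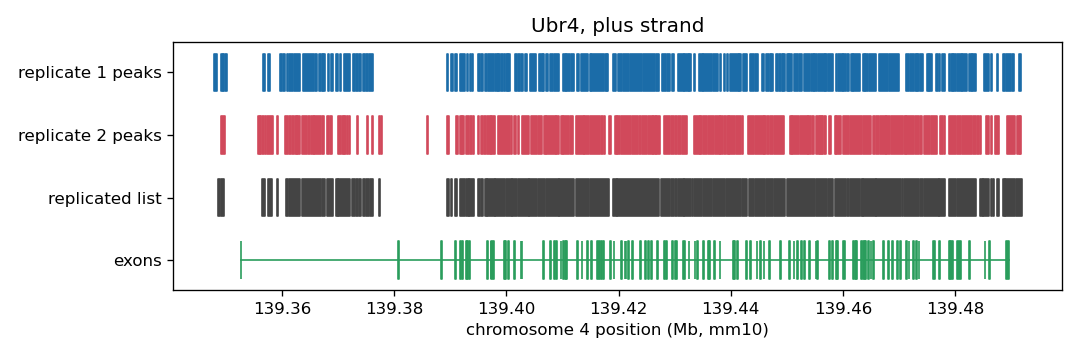
Peaks of replicate 1 (140), replicate 2 (132) and the authors' replicated list (80) as boxes along the Ubr4 region of chromosome 4 (horizontal axis, position in Mb, mm10), above the exons of Ubr4 on the plus strand. Peaks took up most of the gene in both replicates.

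Across genes, the coverage in the replicates was set side by side to ask whether the same genes were widely covered in both pools. Prpf8, a core component of the spliceosome, had 70.0% of its body covered in replicate 1 and 70.8% in replicate 2. Polr2a, which encodes the largest subunit of RNA polymerase II, had 42.3% and 43.4%, and the olfactory receptor gene Olfr1 was at 0 in both. Over 20327 protein-coding genes of at least 2 kb the coverage of the replicates had a Pearson's r of 0.9496 and a Spearman's rho of 0.9225. These correlations are across genes, which are not independent replicates, and 9319 of the genes (45.8%) were at 0 in both. Over the 11008 genes above 0 in a replicate, Pearson's r was 0.928 and Spearman's rho 0.898.

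The authors' pooled and replicated lists were compared to see which peaks the replicated list kept. Zfp68, a zinc finger gene on chromosome 5, held the kept peak with the highest fold enrichment, 10.4, at 138604878 to 138608590. Next came Zfp27 (9.34), 2610008E11Rik (9.17) and Brd2 (8.81), the last a bromodomain protein gene. The remaining genes of the 10 at the top were Zfp329, Eif4g2, Atxn2l, Zfp386, Prr12 and Dhx57, with folds from 8.12 to 8.71, so that 4 of the 10 were Zfp genes. The replicated list held 86209 of the 140664 pooled peaks on the chromosomes, 61.3%, with a Wilson 95% interval of 61.0% to 61.5% that covers counting error only. Kept peaks had a median fold of 3.69 and a median width of 481 bp, against 2.86 and 232 bp for the 54455 that were dropped. Of the kept peaks 66.3% overlapped a peak in both replicate lists, while 25832 overlapped a peak in 1 of them and 3224 in neither. Both lists come from the reads of the replicates, so they are no independent evidence, and the fold and p of each peak are the authors' own values, used here only to rank peaks within a list.

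H3K36me3 peaks were compared between parts of the genome to see which features they occupied. Gene bodies of protein-coding genes held 95.7% ± 0.171 (SD, n = 2) of the peak bases, which was 2.27 ± 0.00819 times the share given by circular shifts. Exons held 28.05% ± 0.0486 of the peak bases, 6.98 ± 0.0347 times chance, and introns held 67.6% ± 0.123, 1.77 ± 0.00617 times chance. The regions within 1 kb of a transcription start site (TSS) held 0.429% ± 0.0118, 0.250 ± 0.00616 times chance, and sequence outside all annotated genes held 3.63% ± 0.185, 0.0712 ± 0.00373 times chance. The 5 kb downstream of gene ends held 3.45% ± 0.0777, 1.135 ± 0.0267 times chance. For gene bodies, exons, introns, TSS regions and intergenic sequence the permutation p in each replicate was 0.001998, two-sided and the smallest that 1000 shifts can give, or 0.0024 after Benjamini-Hochberg adjustment over 6 features in 2 replicates. For downstream sequence the adjusted permutation p, two-sided, was 0.0719 in replicate 1 and 0.0153 in replicate 2, so its excess did not hold in both. With the peaks of −log10 q of at least 2 alone, the mean fold of downstream sequence over the replicates was 0.986. The adjusted permutation p there, 0.865 and two-sided, is that of a single replicate and does not test the mean.

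**Figure D2:**
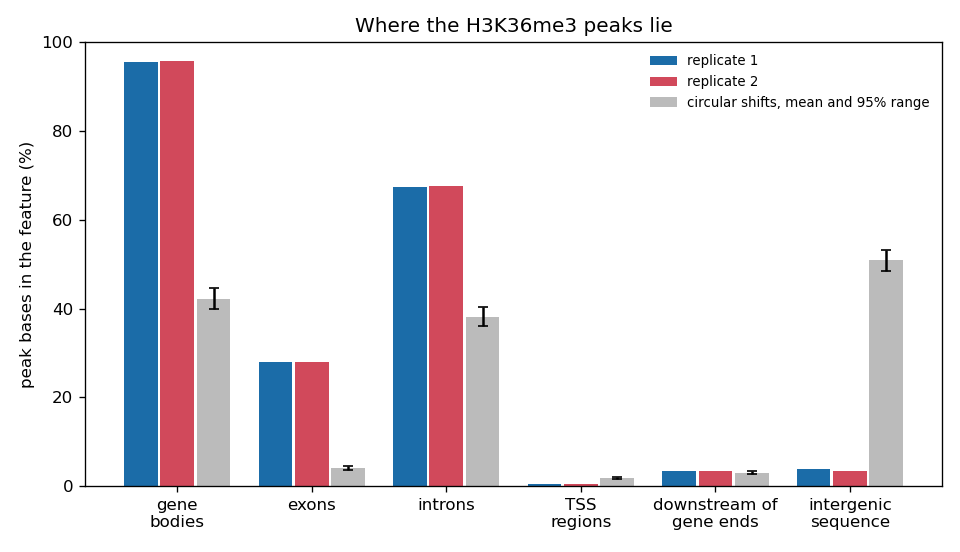
Percent of peak bases (vertical axis) in each kind of sequence (horizontal axis) for replicate 1 and replicate 2, with grey bars for the mean of 1000 circular shifts and their central 95% range. Gene bodies held 95.5% and 95.8% of the bases in the replicates against 42.2% and 42.1% for the shifts.

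Along genes, the question was whether the mark was even from start to end. In marked genes, defined as those of at least 2 kb with at least 20% of the body covered in both replicates, the mark was nearly lacking at the start and rose along the gene. The bin next to the TSS, of 10 equal bins of the gene body, was covered to 2.09% ± 0.285 (SD, n = 2), bin 5 to 40.25% ± 3.55, and bin 8 to 50.3% ± 4.71. The last bin of the gene had 43.7% ± 4.67, the first kb after the gene end 25.6% ± 3.20, and the kb just upstream of the TSS 0.301% ± 0.0983. Over the 1702 marked genes of at least 5 kb that overlapped no other protein-coding gene, coverage of the 3-prime side exceeded that of the 5-prime side by 24.98 ± 2.29 percentage points (SD, n = 2). The difference was positive in 1544 of these genes in replicate 1 and in 1567 in replicate 2. A sign-flip permutation test across genes gave p = 1e-05 in each replicate, two-sided and the smallest that 100000 flips can give. Genes are not independent replicates, so this p describes these libraries.

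**Figure D3:**
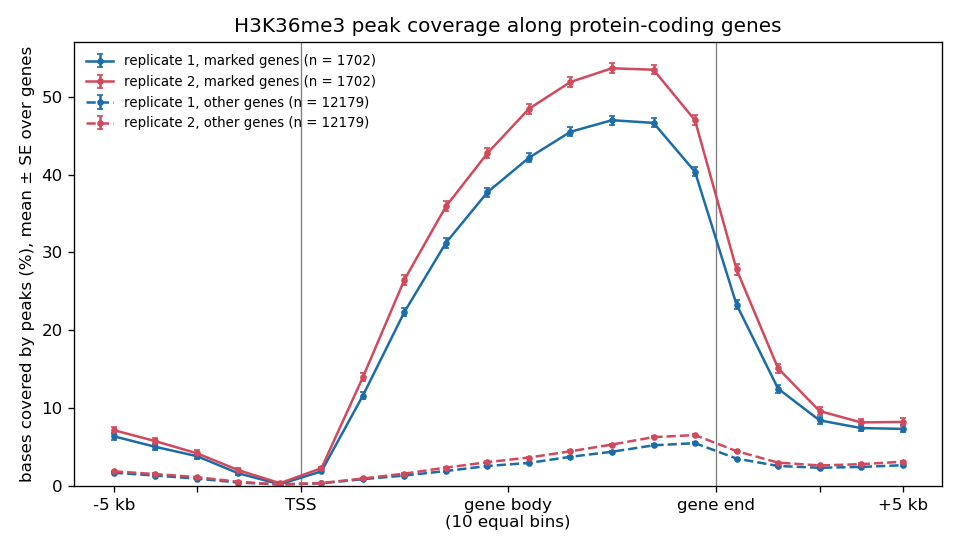
Percent of bases covered by peaks (vertical axis, mean ± SE over genes) in 10 equal bins of the gene body and in 1 kb bins of the 5 kb on either side (horizontal axis), for 1702 marked and 12179 other protein-coding genes in each replicate. Coverage of marked genes rose from 1.89% and 2.29% in the first bin to 47.0% and 53.7% in bin 8.

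Within marked genes, exons were compared with introns, leaving out the first exon. Exonic bases were covered to 49.9% ± 4.24 (SD, n = 2) and intronic bases to 31.5% ± 3.24, a difference of 18.45 ± 0.995 percentage points. Exons were the more covered part in 2109 of 2573 marked genes in replicate 1 and in 2151 in replicate 2. A sign-flip permutation test across genes gave p = 1e-05 in each replicate, two-sided and the smallest that 100000 flips can give. The size of the difference depended on position: in the 3-prime part of the genes, an alternative chosen after the data were seen, it was 6.67 ± 0.0439 percentage points, again with a permutation p of 1e-05, two-sided.

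Marked genes were counted to see which genes carried the mark over a large part of their length. Among the 20327 measured genes, 2591 (12.7%) were marked in both replicates, against a mean of 480.9 and a highest count of 585 in 100 circular shifts. Replicate 1 marked 2807 genes on its own and replicate 2 marked 3383. Ubr4 had 102.5 kb in peaks of the replicated list, followed among marked genes by Macf1, a cytoskeletal linker gene (92.7 kb), Wdfy3, which encodes an adaptor of selective autophagy (90.5 kb), Hectd4 (76.8 kb) and Trrap, a scaffold of histone acetyltransferase complexes (73.6 kb). Trrap had 65.5% ± 7.13 of its body covered (SD, n = 2) and Macf1 22.15% ± 2.57. The other genes of the 10 with the most covered base pairs were Clasp1 and 4930402H24Rik, both marked, and Gm20388, Fgfr2 and Vps13d, which were not. Gm20388 (4434.9 kb) and Fgfr2 (2960.9 kb) are gene models that run across other genes, whose peaks they share. The share of marked genes was highest between 10 and 30 kb of length, at 19.97%, and it was 12.4% from 30 to 100 kb and 2.03% from 100 to 300 kb; beyond 300 kb Macf1 alone was marked, 1 of 566 genes. The count depended on the minimum: 4675 genes passed at 10% and 484 at 40%, 1475 passed with the peaks of −log10 q of at least 2 alone, and 3911 passed on the authors' replicated list.

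The fixed gene lists were then compared with all other measured genes by the share of marked members. These tests count genes, which are not independent replicates, so each p describes these libraries. Genes for RNA splicing factors were marked in 15 of 18 cases (83.3%, against 12.7% of other genes, odds ratio 34.4). Prpf8 had 70.4% ± 0.600 of its body covered (SD, n = 2), the spliceosomal helicase gene Snrnp200 66.45% ± 0.849, Sf3a1 59.75% ± 14.0 and Sf3b2 49.4% ± 1.85. The splicing genes outside the call were Ptbp2, the neuronal paralog of Ptbp1, at 4.42% ± 1.98, Srsf2 at 11.4% ± 5.60 and Srsf1 at 15.2% ± 3.94; Srsf1 was named after its value was seen. Writers, erasers and readers of H3K36 methylation were marked in 8 of 19 cases (42.1%, odds ratio 4.99), among them the demethylase gene Kdm4a at 59.3% ± 7.87, the reader gene Brpf1 at 50.3% ± 1.56, Psip1 at 36.7% ± 7.04 and the methyltransferase gene Nsd1 at 26.9% ± 4.30. In the same list the DNA methyltransferase gene Dnmt3b was at 0.795% ± 0.386 and Phf19, a Polycomb-associated gene, at 0 in both replicates. Zinc finger genes named Zfp were marked in 94 of 390 cases (24.1%, odds ratio 2.22), with Zfp606 at 67.4% ± 14.8, Zfp335 at 61.5% ± 9.41, Zfp105 at 60.9% ± 4.53 and Zfp869 at 60.8% ± 8.68, while Zfp114 and Zfp119b were at 0. The adjusted p of Fisher's exact test, two-sided and over 21 lists, was 2.16e-10 for splicing factors, 5.12e-09 for Zfp genes and 0.00741 for H3K36 factors. The call on the H3K36 factors was lost at a minimum of 40% (2 of 19, odds ratio 4.84, adjusted p = 0.519, Fisher's exact test, two-sided), with stricter peaks (3 of 19, odds ratio 2.40, adjusted p = 0.653) and without genes that overlap another (5 of 13, odds ratio 4.92, adjusted p = 0.0567), while replicate 2 alone marked 12 of 19 (odds ratio 8.61, adjusted p = 2.95e-05) and a minimum of 10% left 14 of 19 (odds ratio 9.40, adjusted p = 1.68e-05). That on the Zfp genes was lost at 40% (14 of 390, odds ratio 1.54, adjusted p = 0.669, Fisher's exact test, two-sided). The median coverage of the list, 42.35% for splicing factors, 22.7% for H3K36 factors and 9.82% for Zfp genes, lay above that of each of 10000 random lists of the same size matched on gene length.

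Mitochondrial ribosomal protein genes were marked in 17 of 74 cases (23.0%, odds ratio 2.05), with Mrpl47 at 41.6% ± 3.28 of the body covered (SD, n = 2), Mrps7 at 37.0% ± 12.8, Mrpl44 at 33.4% ± 0.938 and Mrpl12 at 33.3% ± 8.73, and Mrpl23 and Mrpl36 at 0. Their adjusted p was 0.0563 by Fisher's exact test, two-sided, which missed the threshold, but replicate 2 alone marked 30 of 74 (adjusted p = 4.65e-06) and replicate 1 alone 24 of 74 (adjusted p = 0.000263). With the peaks of −log10 q of at least 2 alone 6.76% of the list was marked, against 7.26% of other genes. Housekeeping reference genes were marked in 5 of 13 cases (38.5%, odds ratio 4.285, adjusted p = 0.0623 by Fisher's exact test, two-sided). These were Polr2a at 42.9% ± 0.780, the beta-actin gene Actb at 42.5% ± 14.3, Tbp at 40.1% ± 6.83, Sdha at 35.35% ± 7.55 and the transferrin receptor gene Tfrc at 34.8% ± 11.6, the last named after its value was seen, while B2m and Ubc were at 0. Without the minimum length the adjusted p was 0.0406 for both lists (Fisher's exact test, two-sided). The median coverage was 15.47% for mitochondrial ribosomal proteins, above that of each of 10000 random lists matched on gene length, and 11.8% for housekeeping genes, above that of 96.6% of such lists. Of 16 genes of the cell cycle and DNA replication, Mcm7 (41.1% ± 16.8), Mcm4 (33.8% ± 5.93) and the cyclin gene Ccna2 (28.3% ± 0.330) were marked and the mitotic genes Aurkb and Ccnb1 were at 0 (18.8% marked, odds ratio 1.58, adjusted p = 0.522, Fisher's exact test, two-sided). Mcm7 and Ccna2 overlap another gene; without such genes 1 of 13 was marked, with an odds ratio of 0.654, and none of the 16 passed a minimum of 40%. None of 997 olfactory receptor genes, best known from sensory neurons of the nose, was marked (adjusted p = 6.97e-60, Fisher's exact test, two-sided), and Olfr1 and Olfr10 were at 0. None of 9 measured replication-dependent histone genes was marked, with Hist1h1d and Hist1h2ac at 0 (adjusted p = 0.679, Fisher's exact test, two-sided); without the minimum length it was none of 67 (adjusted p = 0.0022).

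In the 12 lists of genes restricted to a region or cell type, Msi1 and Hoxa5 were the only marked genes, 2 of 180. Of 13 neural progenitor genes, Msi1, an RNA-binding protein of neural stem cells, was the only one marked, with 34.4% ± 3.09 of its body covered (SD, n = 2), and Fabp7 and Hes1 were at 0. Of 16 pan-neuronal genes, Ina, which encodes the neurofilament protein alpha-internexin, was marked at 30.8% ± 14.0, whereas Gap43 was at 0.106% ± 0.150 and Syt1 at 0.174% ± 0.179; the median coverage of this list, 3.62%, against 0.480% for random lists matched on gene length, lay above that of 94.2% of them. Replicate 2 alone marked 2 of the 16, and none passed with the peaks of −log10 q of at least 2. Of 38 Hox genes, which pattern the body axis from head to tail, Hoxa5 was marked at 50.1% ± 10.8, and Hoxa1 and Hoxa11 were at 0. Ina and Hoxa5 overlap another gene, and without such genes none of 10 pan-neuronal and none of 26 Hox genes was marked. Among the other marked genes named here, Ubr4, Brd2, Dhx57, Psip1, Zfp335, Mrpl47, Mrps7, Mrpl44 and Tbp overlap another gene too. No gene was marked among 16 spinal neuron transcription factors, 12 neurotransmitter genes, 12 genes of floor and roof plate, 12 of the oligodendrocyte and astrocyte lineage, or 13 of sensory ganglia and neural crest. The members at 0 in both replicates included En1, Evx1, Chat, Ddc, Foxa1, Bmp6, Aqp4, Gfap, Foxd3 and Ntrk1. In the remaining lists, none was marked of 14 forebrain and midbrain transcription factors, 13 erythroid and microglial genes, 14 of endothelium, pericytes and mesenchyme, 12 of skeletal muscle and cartilage, or 11 hepatocyte genes. Dlx1, Dlx2, Aif1, Epor, Cdh5, Col1a1, Acan, Acta1, Afp and Ahsg were at 0. Each of these lists alone fell short of the threshold, with adjusted p from 0.247 for Hox genes and 0.487 for the lists with no marked gene up to 0.746 for pan-neuronal and 1 for progenitor genes (Fisher's exact test, two-sided). With no marked gene in 11 to 16, the unadjusted p of that test was still 0.241 to 0.394. Lists of this size could therefore not show too few marked genes, whatever their values. The 12 restricted lists, which leave out pan-neuronal genes, were combined after the data were seen: the share of 1.11% marked was set against 12.85% of other genes, with an odds ratio of 0.0762 and p = 1.39e-08 by Fisher's exact test, two-sided. At a minimum of 40% the combined call was lost (1 of 180, Hoxa5, p = 0.136, Fisher's exact test, two-sided). Replicate 2 alone marked 5 of the 180, adding Hoxa4, Hoxa6 and Hoxb5 to Msi1 and Hoxa5, and replicate 1 alone marked 3, adding Hoxb4; these additions were named after their values were seen.

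**Figure D4:**
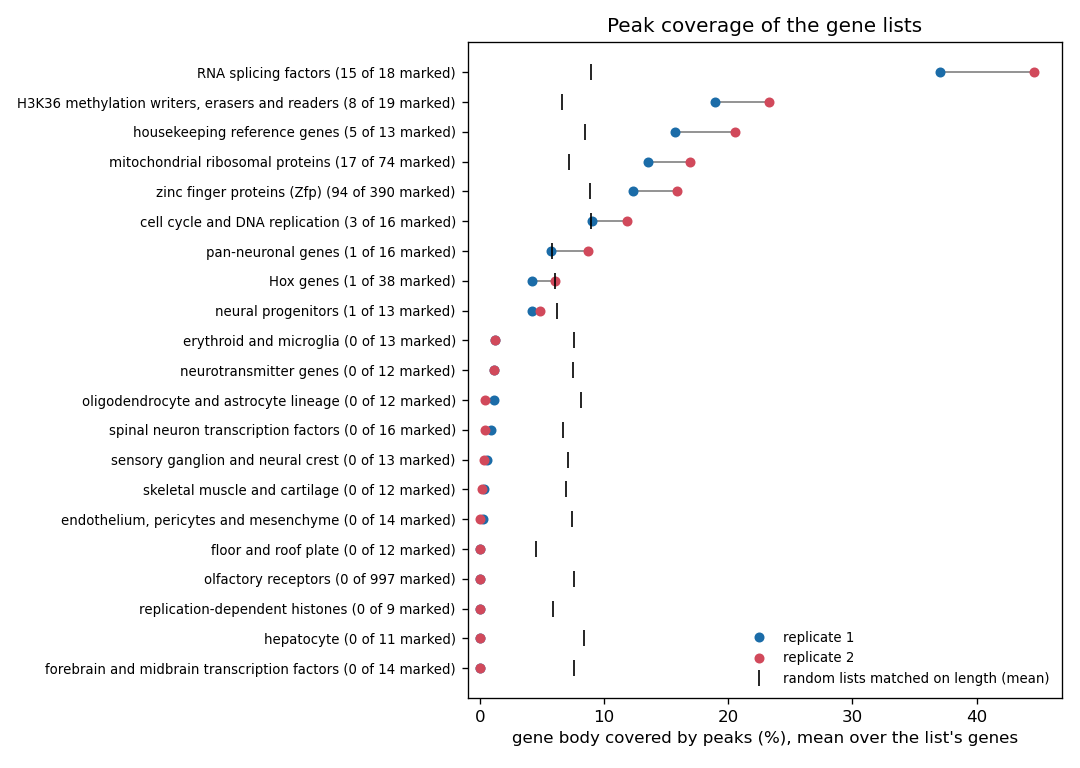
Mean percent of the gene body covered by peaks (horizontal axis) over the measured genes of each fixed list (vertical axis, with the number marked) in replicate 1 and replicate 2, with a tick for the mean of 10000 random lists of the same size matched on gene length. Splicing factors stood at 37.0% and 44.6% against 8.93% for the random lists, and forebrain and midbrain transcription factors and hepatocyte genes at 0.

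The X chromosome was compared with the autosomes within the same pools of both sexes. Of 791 measured genes on X, 4 were marked (0.506%), against 2587 of 19385 autosomal genes (13.3%), an odds ratio of 0.0330. The marked X genes were Ddx3x, which encodes an RNA helicase (31.1% ± 2.64, SD, n = 2), the filamin gene Flna (30.2% ± 9.96), the ubiquitin-activating enzyme gene Uba1 (26.0% ± 3.18) and the histone demethylase gene Kdm5c (24.3% ± 5.83), all named after their values were seen. The lowest share on an autosome was 8.20%, on chromosome 14, and the highest 17.8%, on chromosome 8. Fisher's exact test gave p = 1.06e-41, two-sided, which counts genes and so describes these libraries. Replicate 2 alone marked 13 X genes (1.64%, odds ratio 0.0794), and 17 passed a minimum of 10% (2.15%, odds ratio 0.0694).

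**Figure D5:**
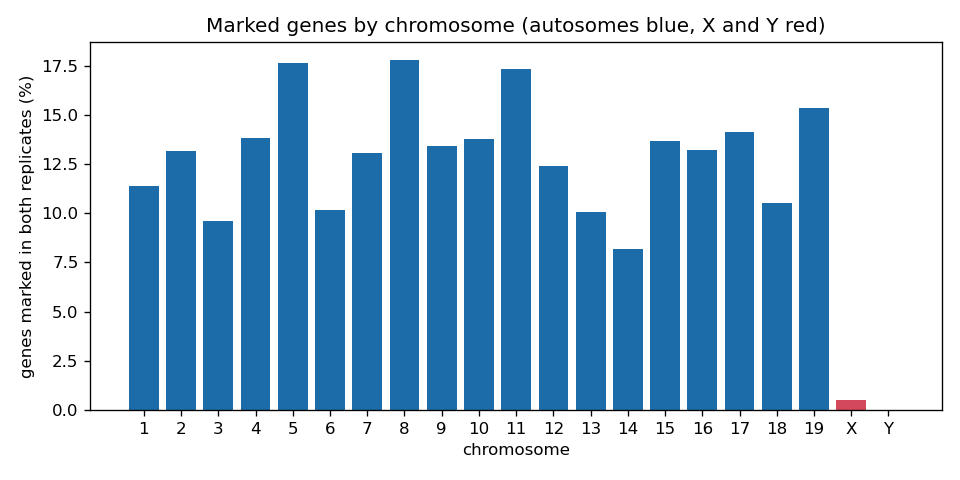
Percent of measured protein-coding genes marked in both replicates (vertical axis) on each chromosome (horizontal axis), with autosomes in blue and X and Y in red. Autosomes lay between 8.20% and 17.8%, X at 0.506% and Y at 0.

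Differences between the replicates were listed per gene as values, since there was 1 library on each side and so no replicate check. Coverage was higher in replicate 2 for 6931 genes and in replicate 1 for 4072. Its mean over genes was 8.07% in replicate 2 and 6.93% in replicate 1. The counts given here carry this offset between the lists and were not redone at equal covered base pairs. The genes with the largest excess in replicate 1 were Vps28 (49.45% against 12.7%), Doc2g (37.2% against 2.90%) and BC037034 (49.7% against 18.1%). Those with the largest excess in replicate 2 were Chkb (41.6% against 0), Pagr1a (46.3% against 9.10%) and Tmem86b (60.7% against 24.0%). All 6 were short, from 2.32 kb to 4.38 kb, so that a few peaks set their coverage. Vps28, Doc2g, Chkb and Pagr1a also overlap another gene, whose peaks they may share. A difference of more than 20 percentage points was seen in 24 genes in favour of replicate 1 and in 137 in favour of replicate 2.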

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

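Of the tests in this part, the combination of 12 gene lists was chosen only after the result was seen. The low share on X was taken up for weighing, in place of exons over introns, after both results were seen.

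Long noncoding RNA genes stood out because no comparison of the report used them: 6 of 4965 that are at least 2 kb long and overlap no protein-coding gene reached 20% coverage in both replicates (0.121%, Wilson 95% interval 0.0554% to 0.263%, counting error only). They were Snhg1 (45.3% ± 22.65, SD, n = 2) and Snhg17 (43.1% ± 17.97), both hosts of small nucleolar RNAs, Mirg (33.9% ± 12.3) and Meg3 (28.0% ± 5.57), both of an imprinted region of chromosome 12, 5430416N02Rik (32.8% ± 7.56) and Lncppara (24.5% ± 4.88), all named after their values were seen. Snhg1 lies 0.105 kb from Slc3a2 and 5430416N02Rik 4.607 kb from Sec31a, and for both the near side of the coding gene is its start; the others lie at least 14.06 kb from a coding gene.

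Genes restricted to a region or cell type were rarely marked, 2 of 180 (1.11%). The 180 include lists that are not of neural cells, such as 11 hepatocyte genes and 12 of skeletal muscle and cartilage. The low share therefore does not describe genes of neural cells alone. Gene length with exon number, and GC content, are argued against as the whole cause, since 10000 random sets matched on length and exon number had 10.65% marked genes (central 95% range 6.67% to 15%) and sets matched on GC content 16.6% (11.7% to 22.2%). The 20% minimum as one that hides partly covered genes is argued against as the whole cause too. In the pooled list 11.1% of the 180 genes had at least 5% coverage, against 30.99% in matched sets (25% to 37.2%). These were 20 genes, while 2 were marked, so the minimum did leave out partly covered genes and may account for part of the pattern. The call did not hold at a minimum of 40%, where 1 of 180 was marked against 2.40% of other genes. Dilution of the mark in a tissue of many cell types may contribute and stays open, and no biological explanation was tested.

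Zfp genes were marked more often than other genes, 94 of 390 (24.1%). Sets matched on gene length, exon number and GC content had 7.99% marked genes (central 95% range 5.64% to 10.51%), which argues against these properties. Reads shared between neighbouring genes named Zfp are argued against by the 168 Zfp genes with no other Zfp gene within 100 kb. Of these, 39 were marked (23.2%, odds ratio 2.09, p = 0.000166 by Fisher's exact test, two-sided). Reads shared with nearby paralogs of other names, or between paralogs far apart, could still contribute and were not tested. The call was lost at a minimum of 40%, and no biological explanation was tested.

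X-linked genes were rarely marked, 4 of 791 (0.506%). Gene length, exon number and GC content are argued against, since 0.382% of the 786 X genes with a match were marked and sets of autosomal genes matched on all of these had 9.95% (central 95% range 8.015% to 11.96%). The kinds of genes on the X chromosome are argued against as well, but only for the X genes that could be tested. Families were symbol stems, whose members need not be related by descent. In 281 families with members on X and autosomes, 3 of 430 X members were marked, against 51.9 (41 to 63) in 10000 shufflings within families. X genes whose stem has no autosomal member did not enter, so for them the explanation stays open. Fewer reads from the X chromosome, which males carry in a single copy, cannot be told apart from less of the mark: the median log2 ratio of the authors' fold of X peaks to autosomal peaks in the same class of −log10 p was 0 in each replicate, with 9.48% of X peaks above and 7.35% below in replicate 1 and 6.35% above and 27.02% below in replicate 2. The lists leave this test little to show, because each −log10 p went with 1 fold in replicate 1 and with at most 2 in replicate 2, so the explanation stays open, and no biological explanation was tested.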

How the results depend on the processing

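Equal covered base pairs, the combination of 12 gene lists, exons and introns without repeats or in the 3-prime part of genes, and chance drawn within gene bodies were chosen only after the results were seen. Of 284 recomputed results, 259 kept their side of the threshold or, where not tested, stayed close to the reported value (within 1 SD between replicates, or 1.5 times for counts). None changed direction past a threshold. The 259 include the overlap of the replicates, intergenic sequence, the rise along genes, exons over introns, and the low share on X under every alternative run for them. They also include the lists of 11 to 16 genes with no marked gene, too small to show fewer marked genes at the reported minimum. That these lists stayed short of the threshold says little about robustness. With the share of the genome as chance, the fold was 2.37 for gene bodies, 7.52 for exons, 1.84 for introns, 0.271 for TSS regions and 1.21 for downstream sequence, each more than 1 SD from the reported fold. With peaks of −log10 q of at least 2, the replicated list kept 75.3% of pooled peaks, Pearson's r across genes was 0.911, 1475 genes were marked, and the H3K36 factors had an adjusted p of 0.653 (Fisher's exact test, two-sided, as for all adjusted p here). With equal covered base pairs Pearson's r was 0.941. A minimum of 10% gave 4675 marked genes and an adjusted p of 5.62e-08 for mitochondrial ribosomal proteins. A minimum of 40% gave 484 marked genes and adjusted p of 0.519 for H3K36 factors and 0.669 for Zfp genes, and p = 0.136 for the combined lists (Fisher's exact test, two-sided); fewer genes pass it by construction. On the replicated list 3911 genes were marked and the adjusted p of mitochondrial ribosomal proteins was 1.32e-08. Without the minimum length the adjusted p was 0.0406 for housekeeping genes, 0.0406 for mitochondrial ribosomal proteins and 0.0022 for replication-dependent histones, of which more genes are then tested. Without genes that overlap another, it was 0.0567 for H3K36 factors. With a replicate left out, the fold of downstream sequence ranged from 1.117 to 1.154, and the adjusted p of mitochondrial ribosomal proteins from 4.65e-06 to 0.000263, where a gene needs to pass in 1 library only. Over all alternatives the adjusted p ranged from 1.68e-05 to 0.653 for H3K36 factors, from 1.07e-21 to 0.669 for Zfp genes, from 1.32e-08 to 1 for mitochondrial ribosomal proteins, and from 0.0406 and 0.0022 to 1 for housekeeping genes and histones (Fisher's exact test, two-sided); that of splicing factors did not exceed 1.11e-06. Where no reason is given here, the cause was not tested. Counting any overlap as kept changed nothing, since the replicated peaks are pooled peaks. The unknown depth limits what absence of a peak shows: a gene at 0 had no called peak, which does not exclude the mark.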

Other observations

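All tests in this part were chosen only after the data were seen. Other than Hoxa1, Hoxa5 and Hoxa11, the genes named here fall outside the rule for named genes and were named after their values were seen. Genes were also grouped by the stem of their symbol, and 137 stems with at least 15 measured genes were compared with all other genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment; 18 stems had more marked genes and 8 had fewer. The stems Olfr, Zfp, Mrpl and Mrps are also covered by the fixed lists, and Zfp counts among the 18 and Olfr among the 8. A shared stem does not ensure common descent, and genes are not independent replicates. Among the stems with more, 24 of 37 Ddx helicase genes were marked (odds ratio 12.75, adjusted p = 9.35e-12, Fisher's exact test, two-sided), 11 of 16 Dhx helicase genes (odds ratio 15.1, adjusted p = 6.53e-06), 27 of 54 translation initiation factor genes named Eif (odds ratio 6.91, adjusted p = 1.25e-09) and 23 of 44 ribosomal protein genes named Rpl (odds ratio 7.55, adjusted p = 8.97e-09). Also among these stems were 14 of 27 RNA polymerase subunit genes named Polr, 12 of 21 nucleoporin genes named Nup and 10 of 15 Integrator subunit genes named Ints. The stems with fewer held none of 269 vomeronasal receptor genes named Vmn (adjusted p = 1.39e-14, Fisher's exact test, two-sided), none of 53 keratin genes named Krt (adjusted p = 0.00899), none of 45 collagen genes named Col (adjusted p = 0.0188), 1 of 99 Cyp genes, namely Cyp51, a gene of cholesterol synthesis (adjusted p = 0.00057), and 25 of 370 solute carrier genes named Slc (odds ratio 0.491, adjusted p = 0.00247).

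Coverage within the Hox clusters is given as values without a test. In the a cluster Hoxa5 had 50.1% ± 10.8 of its body covered (SD, n = 2), Hoxa4 20.6% ± 1.39, Hoxa6 19.8% ± 12.4 and Hoxa3 12.1% ± 4.62, and Hoxa1, Hoxa2, Hoxa7, Hoxa11 and Hoxa13 were at 0. In the b cluster Hoxb5 had 28.2% ± 22.6, Hoxb4 19.4% ± 3.80, Hoxb8 7.81% ± 0.145, Hoxb3 5.76% ± 1.58, Hoxb2 4.96% ± 7.01 and Hoxb6 3.17% ± 1.38, and Hoxb1, Hoxb7, Hoxb9 and Hoxb13 were at 0. In the c cluster none exceeded 2.65%, the value of Hoxc6, and in the d cluster the highest were Hoxd3 at 8.50% ± 3.55 and Hoxd4 at 7.61% ± 5.10, with Hoxd8 to Hoxd13 at 0. Neighbouring Hox genes lie close together and some gene models overlap, so a peak can count for more than 1 of them.

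Of the 86209 peaks of the replicated list on the chromosomes, 2582 (2.995%) lay wholly outside annotated genes. Their median authors' fold was 3.40 and their median width 399 bp, against 3.69 and 485 bp for the others. None of 151 measured genes on Y was marked, and Y held 4 peaks in replicate 1 and 3 in replicate 2.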
